A study of Mus musculus with 9 samples.

How the data were processed

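Whole ovaries of C57BL/6J mice, an inbred laboratory strain, were profiled by RNA sequencing at 15 weeks of age, after 10 weeks on a diet. Per the labels, 3 mice were fed standard chow with 16% fat (control) and 6 were fed a 60% fat diet. The diet-fed mice fell into 2 groups of 3 by body weight: those that stayed lean (HFLN) and those that became obese (HFOB). Membership of HFLN and HFOB was thus set by the response of the animal to the diet and not by assignment. Ovaries were snap-frozen, RNA was taken up on silica columns, and libraries were made with a strand-specific kit that selects messenger RNA, per the labels' protocols.

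The submitters' processing notes name Trimmomatic 0.32.3, TopHat2 2.1.0, Cufflinks 2.2.1.0 and Cuffdiff 2.2.1.3, with genome build mm10. These tools trim reads, align them across splice junctions, assemble transcripts and estimate their abundance. The annotation, the scaling between libraries and the strand setting are not given in the sources used here, so a gene and an overlapping partner on the opposite strand may share reads. The table used here holds, per the file headers, the authors' FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments) for each gene. The authors deposited 1 FPKM per group, with the animals of a group combined, a lower and an upper bound in FPKM, and a status. Where the status was OK, the bounds lay symmetrically about the value unless the lower one was held at 0. In 6 group values of 5 rows with the status FAIL, Col1a2 in HFOB among them, the upper bound lay below the value. The confidence level of the bounds is not given in the sources used here. Values of single animals were not analysed here, so the spread between animals enters only through those bounds, and no SD, n or p-value is given for any value. How many of the 3 animals in a group carry a difference is unknown.

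The table had 33450 rows. Of its 36886 RefSeq transcript identifiers, 99.2% matched the RefSeq annotation of GRCm38.p6, the assembly that mm10 is made from, and took their gene symbols from it. No symbol was found for 8920 rows, nearly all of them loci assembled by the authors without an identifier, and 765 rows merged several symbols. Coordinates given are the gene's span in the RefSeq annotation of GRCm38.p6, counted from 1. Of the protein-coding rows with 1 symbol, 98.9% overlapped the annotated gene. A row covers a whole gene, with all its exons, and not a single isoform.

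The design had been fixed before the data were examined, with a linear model planned for per-animal FPKM and a rule without a test planned for a table of group values. The second was used. Folds were computed on the log2(FPKM + 1) scale, which understates the difference of low genes. A row passed when its fold was at least 2 on that scale and the deposited intervals of both groups did not overlap. Only rows with at least 1 FPKM in 1 or more groups and a status of OK in the groups compared were considered, which left 16929 to 16932 rows per comparison. Of all rows with at least 1 FPKM, 13657 were protein-coding. A status other than OK was found in 6 rows. Ratios quoted as fold without the log2 scale are plain ratios of deposited FPKM, and a gene listed at 0 was given no ratio.

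The genes named were chosen by a rule fixed before the data were examined: per comparison, the 6 passing genes with the highest and the 6 with the lowest log2 fold, the 2 members with the widest log2 fold in each gene list that stood out or held a passing gene, and a fixed panel of 14 ovarian and adipose genes. Predicted genes, small RNA and rows without a symbol were counted and not named by that rule. For the genes passing in both comparisons with control, the mean of both log2 folds set the order. Genes named beyond the rule were chosen after their values were seen: the protein-coding genes that pass but rank below the sixth, the further list members given as examples, and the abundant genes and small RNA in the closing section. Some genes that met these rules are not reported here.

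Fixed beforehand were also 26 lists of cell-type markers and pathways. The ovulation list and the fixed panel were not blind to the study, since its report was recalled to discuss Edn2 and Tnfaip6. For each list, the median log2 fold was placed as a percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood out when it lay outside the central 95% of them. The percentile describes these group values. Random genes vary independently while genes of a list often vary together, so more than 5% of lists can stand out with no effect of diet. After the table was seen, 4 details were settled: lists used protein-coding rows only (which left out Mx1, annotated as a pseudogene in this strain's genome), each symbol took its row with the highest mean FPKM, members that share a row counted once, and random lists were drawn from 13882 protein-coding symbols. The third of these was changed after a first run had shown the lists' values, and it reduced the erythrocyte list to 4 measured rows. Rows that merge genes are uncertain for each gene: Akr1c18 shares a row with Akr1c12, Hba-a1 with Hba-a2, Hbb-bs with Hbb-b1, Ifit3 with Ifit3b, Pdia4 with a microRNA gene, and Igf2bp1 with another.

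Both comparisons with control share the control values. Unchanged groups were therefore simulated 200 times around the mean FPKM of each row, once with a spread as wide as the deposited intervals (taking them to span 2 SD on either side) and once with that spread multiplied by 0.288, which gives the interquartile range of log2 folds seen between HFOB and HFLN. Simulated intervals kept the full deposited width in both settings. With the scaled spread an unchanged row can therefore hardly pass, and a count of 0 there was fixed by the setting. A group listed at 0 with an interval from 0 to 0 had a spread of 0, so rows like it are hardly reproduced.

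The calling rule was tested on simulated data and the list percentile on randomly drawn genes. With 200 of 16929 rows lowered in HFLN and the scaled spread, the rule found 8.0% of rows lowered by a factor of 2, 78.0% at a factor of 4 and 92.0% at a factor of 8, with 0 unchanged rows passing. The intervals again kept their full width, so this count of 0 was fixed by the setting. With the spread of the deposited intervals it found 30.0%, 68.0% and 88.0%, with 55 unchanged rows passing. For the list percentile, 300 lists of 12 genes were drawn at random from the observed folds of HFLN against control. Of these, 5.3% fell outside the central 95%, close to the share that random draws build in. All lists shifted by 0.3 on the log2 scale were found. Genes that vary together were not part of this check.

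Depth per animal is unknown. The lowest values, multiplied by transcript length in kilobases, were most frequent at 0.0105 in control, 0.0115 in HFLN and 0.0105 in HFOB, without clean steps of whole reads, so the FPKM of a single read and the read numbers were not recovered. The median half-width of the deposited interval was 42.1% of the FPKM in control, 41.3% in HFLN and 41.7% in HFOB among rows of at least 5 FPKM. The alternatives tried were other pseudocounts, low-value filters, scalings, interval rules and fold limits, summed rows, and list means; added after the data were seen were protein-coding rows only, leaving out merged rows, and removal of the trend with transcript length and GC content. Lengths and GC content came from GENCODE M21 transcripts, which covered 98.0% of the protein-coding symbols used. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.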

Results

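Ovarian RNA of 9 mice was measured: 3 fed chow (control), 3 that stayed lean on a high-fat diet (HFLN) and 3 that became obese on it (HFOB). The series asks whether exposure to a high-fat diet, with or without obesity, goes with altered expression of ovarian genes. All values are the authors' FPKM, 1 per group with the deposited interval, without per-animal values or a test. Of the summed FPKM, rows without a gene symbol held 42.2% in control, 27.6% in HFLN and 36.8% in HFOB. Most of this difference lay in 10 loci of at most 493 bp, chosen after the values were seen by their highest mean FPKM. Without them the same shares were 20.3%, 19.0% and 21.2%. FPKM are scaled to length, so short loci weigh more in these sums than in the RNA itself. Rows of at least 1 FPKM numbered 16148 in control, 16310 in HFLN and 16172 in HFOB.

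Mice that stayed lean on the high-fat diet were compared with chow-fed controls to ask what the diet goes with in the absence of obesity. Expression was lower in HFLN for the ovulation genes Edn2 and Tnfaip6 and for genes of the early transcriptional response to stimuli. Edn2, which encodes the vasoconstrictor peptide endothelin-2, stood at 52.1 FPKM in control (deposited interval 23.3 to 80.9) and 3.27 in HFLN (0.893 to 5.64), 15.9-fold lower. Sprr1a, a small proline-rich protein of the cornified envelope, stood at 44.8 (18.0 to 71.5) against 0.664 (0 to 1.42). Odaph, a phosphoprotein first described in tooth development, had 8.24 FPKM in control and 0.240 in HFLN. Tnfaip6, a hyaluronan-binding protein of the matrix around the ovulating oocyte, was 6.81-fold lower in HFLN, at 7.47 against 1.10 FPKM. The immediate-early genes Arc and Fosb were 6.11-fold and 5.33-fold lower. Srxn1, which repairs oxidised peroxiredoxins, stood at 55.4 FPKM (26.4 to 84.5) in control and 17.4 (11.3 to 23.6) in HFLN.

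In all, 48 rows passed the rule in HFLN against control, 11 higher and 37 lower. Protein-coding genes made up 13 of them, 2 higher and 11 lower. Besides those named so far, the lower ones included Brinp2, Dusp5 (a phosphatase of ERK kinases) and the histone gene H3c2. Both higher ones are uncertain. Pramel51 was listed at 0 in control and at 16.5 FPKM in HFLN, but another row of the same gene held 5.69, 6.56 and 6.83 FPKM in control, HFLN and HFOB. The row at 7.84 FPKM in HFLN and 0.0365 in control merges Igf2bp1 with a microRNA gene inside it. A further 14 rows were small RNA genes, 10 of them lower, and 21 had no symbol, 16 of them lower. Among the small RNA genes, the structural RNA Rmrp stood at 441 FPKM in control, 41.2 in HFLN and 258 in HFOB, and Rpph1 at 345, 46.2 and 256. H3c2 was likewise lowest in HFLN, and 47 of 53 measured replication-dependent histone genes were lower in HFLN than in control. A group was listed at 0 in 18 of the 48 rows. In simulations of unchanged groups, a mean of 67.0 rows passed with the spread of the deposited intervals, so the count alone lies within what that spread allows. That spread was wider than the data. Among rows of at least 5 FPKM, log2 folds of HFOB against HFLN had an interquartile range of 0.589 in it and 0.170 as observed. With the spread scaled to the data 0 rows passed, which the full-width intervals fixed in advance. Neither setting therefore shows whether the count differs from that of unchanged groups.

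Among the fixed gene lists, 10 of 26 stood out in HFLN against control. All 12 immediate-early genes were lower, with a median log2 fold of -0.84, below all 10000 matched random lists. Fosb passed the rule, and Junb stood at 82.5 FPKM in control and 33.98 in HFLN. All 11 measured interferon-response genes were higher, with a median of 0.72, above all random lists, and none passed the rule: Ifit3 stood at 5.99 against 14.7 FPKM and Ifit1 at 3.03 against 6.50. All 11 measured markers of oviduct epithelium and motile cilia were also higher in HFLN, with a median of 0.55. Sec14l3 had 5.06 FPKM in control and 12.6 in HFLN, and Foxj1, the master regulator of motile cilia, 19.4 and 33.5. The 8 markers of the surface epithelium were all higher, with a median of 0.22, led by Krt18 and Cdh1 at log2 folds of 0.37 and 0.36. Genes of cholesterol synthesis were lower in 15 of 19 cases, with a median of -0.22. Dhcr7, an enzyme of that pathway, was among the higher ones, at 50.8 FPKM in control and 64.3 in HFLN. The 4 measured rows of red blood cell genes were all lower, with a median of -0.71, and the row of Hbb-bs and Hbb-b1 stood at 178.6 against 98.2 FPKM.

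The remaining lists that stood out in HFLN moved less. Circadian genes had a median of 0.21, with 11 of 16 higher: the clock output gene Dbp stood at 32.1 FPKM in control and 53.2 in HFLN, while Nfil3, a repressor of such genes, stood at 35.0 and 16.8. Ovulation genes had a median of -0.11 at percentile 0.94, with 10 of 15 lower and Edn2 and Tnfaip6 passing. Without these 2 genes the list lay at percentile 5.26, inside the central range. With both genes kept and the trend in length and GC content removed, its median was -0.22 at percentile 0. Cell-cycle genes had a median of -0.09, with Plk1 and Cdk1 at log2 folds of -0.31 and -0.25. Stromal matrix genes had a median of 0.05 but a mean of -0.09, since Timp1, an inhibitor of matrix proteases, stood at 597 FPKM in control and 192 in HFLN while Col6a1 and most others were slightly higher. The cell-cycle and circadian lists lay inside the central range when the mean replaced the median, at percentiles 4.01 and 96.1, as did the stromal list with the trend in length and GC content removed, at 94.2. The oxidative-stress list did not stand out, at a median of -0.13, although Srxn1 passed and Hmox1, which breaks down haem, stood at 86.1 against 45.8 FPKM.

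Mice that became obese were compared with the same controls. Most genes that passed were lower in HFOB, and Lep, which encodes the adipocyte hormone leptin, was the 1 protein-coding gene higher, at 0.223 FPKM (0 to 0.455) in control and 2.101 (0.759 to 3.44) in HFOB. Among protein-coding genes Sprr1a again had the lowest log2 fold, at 0.0977 FPKM (0 to 0.304) in HFOB. Edn2 stood at 2.34 FPKM (0.549 to 4.13), 22.3-fold below control, Odaph at 0.146 and Tnfaip6 at 0.848, 8.81-fold below. Wnt7b, a secreted Wnt ligand, was 7.11-fold lower, at 7.84 FPKM in control and 1.10 in HFOB, and Arc was 7.19-fold lower. In all, 62 rows passed, 16 higher and 46 lower. Of these, 24 were protein-coding, 18 were small RNA genes and 20 had no symbol, and 24 had a group at 0. In simulations of unchanged groups, a mean of 65.9 rows passed with the deposited spread and 0 with the scaled one, where the full-width intervals fix that count. Besides those named, the lower protein-coding genes included Fosb, Srxn1, Brinp2, Dusp5, Rem2, Cdkn1a, Nr4a1, Ier3, Ptprn, Csrnp1, Errfi1, Sema4f, Rnf152, Prkg2, Adamts1 and H3c13.

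In HFOB against control 14 of 26 lists stood out. The 12 immediate-early genes were all lower with a median of -0.78, and Fosb and Nr4a1 passed. Nr4a1, an orphan nuclear receptor, stood at 42.8 FPKM in control and 15.3 in HFOB. All 19 measured genes of cholesterol synthesis and uptake were lower, with a median of -0.42, and none passed: Cyp51, a sterol demethylase, stood at 35.9 against 23.1 FPKM. All 13 genes of the endoplasmic reticulum stress response were lower, with a median of -0.30. Ddit3, a transcription factor of that response, stood at 106 against 55.5 FPKM and its target Trib3 at 4.42 against 2.36. The adipocyte list had a median of 0.39 with 7 of 13 members higher and 6 lower. Beside Lep, Fabp4, the fatty-acid binding protein of adipocytes, stood at 77.2 against 139.3 FPKM. Whole-ovary values do not show which cells, or which tissue on the dissected ovary, the adipocyte RNA came from, and this was not tested. Ovulation genes had a median of -0.28 with 10 of 15 lower, and Edn2, Tnfaip6 and the matrix protease Adamts1 passed. Without Edn2 and Tnfaip6 this list stayed outside the central range. The oviduct and cilia markers were lower in HFOB in all 11 cases, with a median of -0.29, and Tmem212 and Sntn stood at log2 folds of -0.85 and -0.64.

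Further lists that stood out in HFOB against control were theca and steroid synthesis at a median of -0.19, luteal genes at -0.25, erythrocyte genes at -0.25, circadian genes at 0.16, fatty-acid synthesis at -0.15, apoptosis at -0.12, the cell cycle at -0.09 and oocyte genes at 0.06. Cyp17a1, which makes androgen precursors in theca cells, stood at 346 FPKM in control and 191 in HFOB, and Fdx1, an electron donor of mitochondrial P450 enzymes, at 974 and 668.5. Hsd17b7, an enzyme of luteal cells that also acts in cholesterol synthesis, stood at 103.9 and 63.1, and the row of Akr1c18 at 2672 and 1496 with intervals that reach 0. Cdkn1a, an inhibitor of cyclin-dependent kinases, passed at 49.9 against 16.3 FPKM, while Fas was at 2.84 against 3.67. The apoptosis list lay at percentile 2.52, just inside the central range, with a pseudocount of 0.1 FPKM. Hbb-bs stood at 178.6 against 129.8, Dbp at 32.1 against 61.7, and Nfil3 at 35.0 against 16.2. Dgat2 and Elovl6 of the fatty-acid synthesis list differed in opposite directions, at log2 folds of 0.57 and -0.47. Ccnb1 and Cdk1 stood at -0.23 and -0.18, and the oocyte genes Mos and Dppa3 at 0.25 and 0.19. Of these lists, the mean brought the cell cycle to percentile 8.85, circadian genes to 96.65, erythrocyte genes to 2.79 and fatty-acid synthesis to 6.58, inside the central range, and removal of the length and GC trend brought erythrocyte genes to 3.39. Srxn1 passed in the oxidative-stress list, whose median was -0.05.

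**Figure D1:**
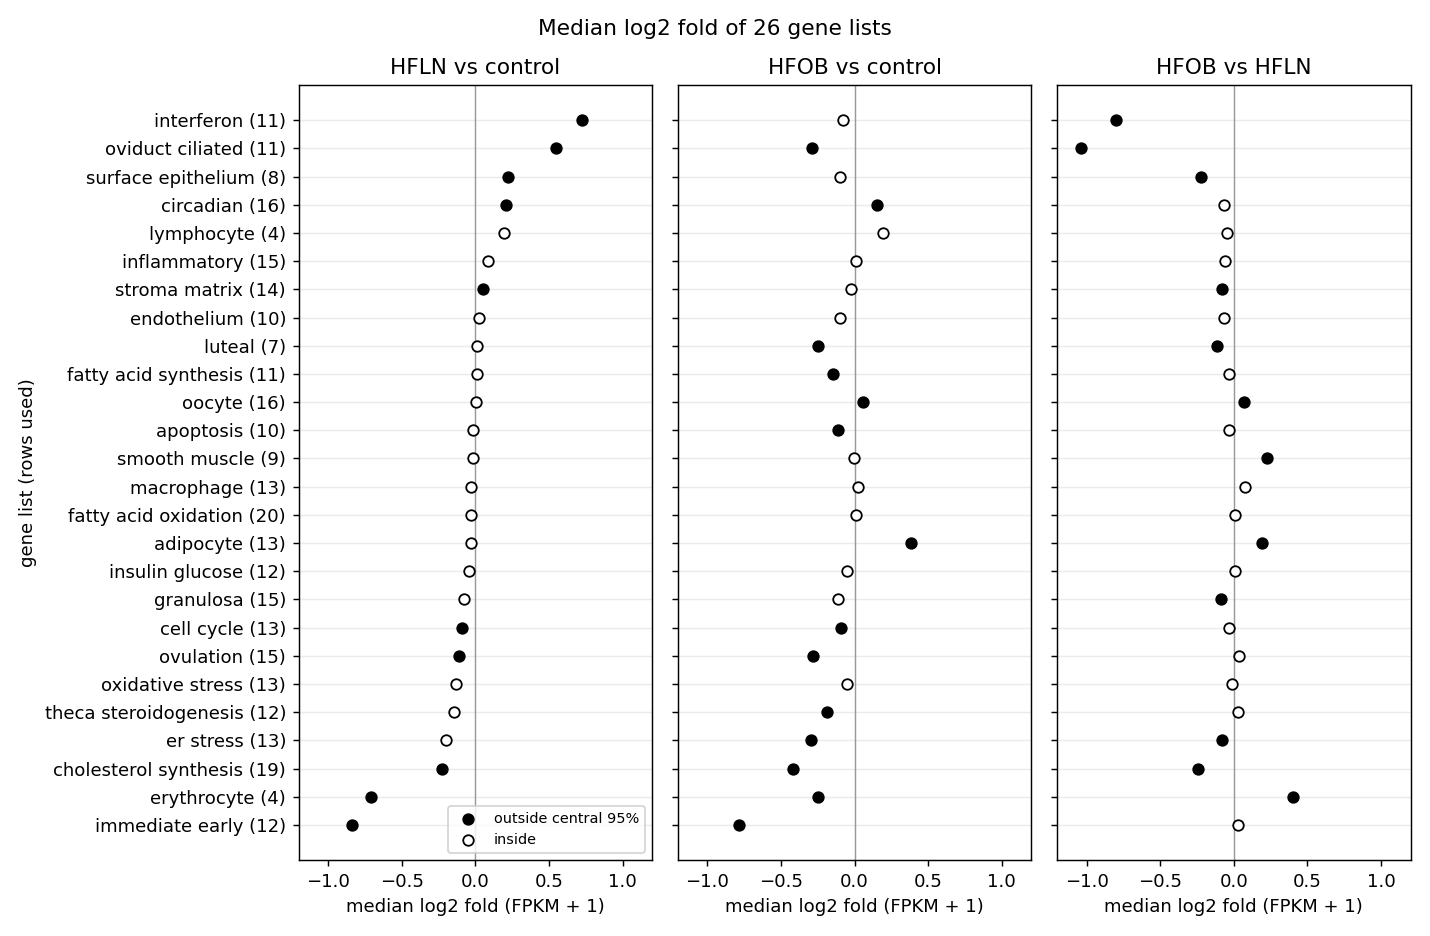
Median log2 fold, on the FPKM + 1 scale, of 26 fixed gene lists in HFLN against control, HFOB against control and HFOB against HFLN, with the number of table rows used in brackets. Filled points lie outside the central 95% of 10000 matched random lists: 10, 14 and 12 lists, with immediate-early genes at -0.84 and -0.78 in the comparisons with control.

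The overlap of both comparisons with control was used to ask about diet exposure regardless of obesity, which a shared control cannot settle. In total 23 rows passed in both in the same direction, 1 higher and 22 lower, and 0 passed in opposite directions. Of these rows 10 were protein-coding and all 10 were lower, among them Sprr1a (chromosome 3, 92483954 to 92485881), Edn2 (chromosome 4, 120161206 to 120167360), Odaph (chromosome 5, 91987473 to 91995317), Tnfaip6 (chromosome 2, 52038113 to 52056681), Arc (chromosome 15, 74669081 to 74672570), Fosb (chromosome 7, 19302696 to 19310118), Srxn1, Brinp2 and Dusp5. The positions are the spans of the genes in the RefSeq annotation of GRCm38.p6. Mean log2 folds ran from -5.08 for Sprr1a to -1.32 for Dusp5. Lists of these sizes that were independent would share 0.0104 higher and 0.101 lower rows. Simulated unchanged groups that share the control values had a mean of 5.68 rows in common and at most 14 with the deposited spread. The count of 0 with the scaled spread was fixed by the full-width intervals. Some of the 23 rows had a group at 0 with an interval from 0 to 0. Snord83b, for example, stood at 290 FPKM in control and 0 in both diet groups. The simulation hardly reproduces such rows, so 23 against 14 does not show an excess. Control values enter both comparisons and cannot be split here, so part or all of the overlap may come from them.

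**Figure D2:**
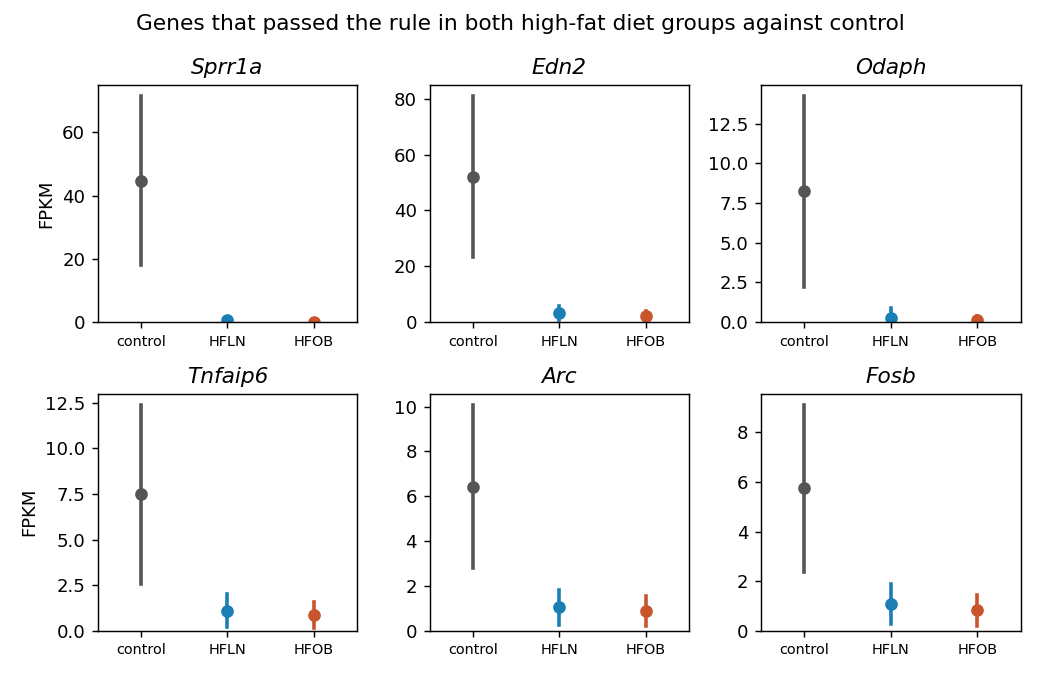
Authors' FPKM (points) with the deposited intervals (bars) in control, HFLN and HFOB for the 6 named protein-coding genes with the lowest mean log2 fold among those that passed in both high-fat diet groups against control, each panel with its own linear axis from 0. In every panel both diet groups lie below the control interval, as for Edn2 at 3.27 and 2.34 against 52.1 FPKM.

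Across 16929 rows the log2 folds of both comparisons with control correlated with a Pearson r of 0.558 and a Spearman rho of 0.526. Genes are not independent replicates, and unchanged groups sharing the same controls gave an r of 0.550 with the deposited spread and 0.588 with the scaled spread. The covariance was 0.0566, against 0.342 and 0.0538 in these simulations. For protein-coding rows it was 0.0279, against 0.268 and 0.0438. The observed r lay between the simulated values, and the covariance of protein-coding rows lay below both.

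Obese and lean mice on the same diet were compared directly. Lep was 6.33-fold higher in HFOB, at 2.101 FPKM (0.759 to 3.44) against 0.332 (0.0392 to 0.625). The histone genes H3c2 and H2ac13 were higher in HFOB, at 4.28 against 0.260 and 2.12 against 0.369 FPKM. Lower in HFOB were the uncertain rows of Pramel51 and Igf2bp1 described above and Ccl21c, a lymphoid chemokine gene present in several near-identical copies, at 0.0160 against 1.82 FPKM. These 6 were the protein-coding genes among 33 passing rows, 19 higher and 14 lower. Small RNA genes accounted for 15 rows and rows without a symbol for 12, and a group was at 0 in 17. With groups simulated as unchanged, a mean of 64.6 rows passed with the deposited spread and 0 with the scaled one, again fixed by the full-width intervals. Edn2, Sprr1a and Tnfaip6 did not pass, at log2 folds of -0.35, -0.60 and -0.18.

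Of the lists, 12 of 26 stood out between HFOB and HFLN. Oviduct and cilia markers had the lowest median, -1.04, with all 11 lower in HFOB: Tmem212 stood at 29.4 FPKM in HFLN and 10.9 in HFOB, and Sec14l3 at 12.6 and 4.35. All 11 interferon-response genes were lower in HFOB, with a median of -0.80, and none passed. Ifit3 stood at 14.7 and 6.41 FPKM and Usp18 at 9.06 and 3.92. Surface epithelium markers were lower in 7 of 8 cases with a median of -0.22, such as Krt7 at 48.3 and 32.7 FPKM. Cholesterol synthesis genes were lower in 16 of 19 cases with a median of -0.25, Dhcr7 at 64.3 and 41.8 FPKM and Hmgcs1 at 103.0 and 75.9. All 9 smooth muscle genes were higher in HFOB, with a median of 0.22, including Des at 49.0 and 60.3 FPKM and Lmod1 at 13.1 and 16.1. The adipocyte list had a median of 0.19, where Lep was higher and Cidea was lower at 3.38 and 1.36 FPKM. All 4 erythrocyte rows were higher, with a median of 0.40 and Hbb-bt at 3.14 and 4.92 FPKM.

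Medians of the remaining lists that stood out between HFOB and HFLN were small. They were -0.12 for luteal genes, -0.08 for granulosa genes, -0.08 for the endoplasmic reticulum stress response, -0.08 for stromal matrix and 0.07 for oocyte genes. Among them Hsd17b7 stood at 104.9 FPKM in HFLN and 63.1 in HFOB, Inhba at 63.1 and 50.2, Pdia4 at 234.4 and 195.3, Calr at 723 and 615, Postn at 14.5 and 17.4, and Fn1 at 110.9 and 93.6. The oestrogen receptor gene Esr2 stood at 31.3 and 38.6 FPKM with intervals that reach 0, and Akr1c18 at 1084 and 1496. Removal of the trend with length and GC content brought granulosa, luteal and oocyte genes to percentiles 2.92, 3.42 and 94.8, inside the central range, and the mean brought granulosa genes to 5.24.

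**Figure D3:**
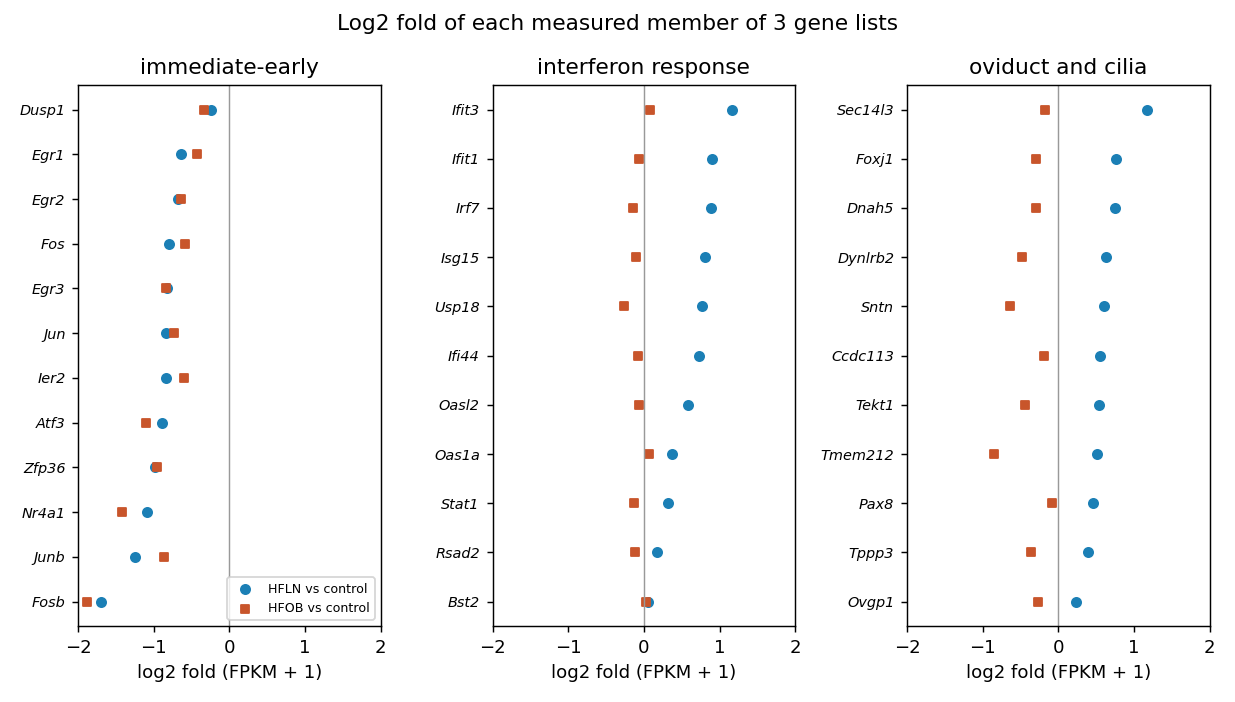
Log2 fold, on the FPKM + 1 scale, of each measured member of the immediate-early, interferon, and oviduct and cilia lists in HFLN (circles) and HFOB (squares) against control. Immediate-early genes lie left of 0 in both groups (medians -0.84 and -0.78), while interferon genes lie right of 0 in HFLN (median 0.72) and near it in HFOB (median -0.08).

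Genes of the fixed ovarian panel differed less than the rule asks, apart from Edn2, Tnfaip6 and Lep. Star, which carries cholesterol into mitochondria, stood at 147 FPKM in control (83.6 to 211), 230 in HFLN (84.1 to 377) and 169 in HFOB (86.6 to 251). Cyp11a1, the first enzyme of steroid synthesis, stood at 3608, 3054 and 3120 with intervals that reach 0. Cyp17a1 stood at 346 (154 to 539), 183.5 (97.51 to 269) and 191 (103 to 280), and the aromatase gene Cyp19a1 at 20.7 (13.3 to 28.0), 14.5 (8.60 to 20.3) and 12.2 (7.36 to 17.0). The gonadotropin receptor genes Lhcgr and Fshr stood at 133.7, 143.0 and 103.7 FPKM and at 16.8, 13.7 and 15.4. Amh, the hormone of growing follicles, stood at 181, 176 and 187, the oocyte genes Gdf9 at 51.4, 50.7 and 56.3 and Zp3 at 52.2, 53.0 and 54.4. Ptgs2, a prostaglandin synthase induced at ovulation, stayed under 1 FPKM in every group, at 0.779, 0.233 and 0.266, and was not considered. The adipocyte hormone gene Adipoq stood at 14.7, 11.9 and 21.5 FPKM. The intervals of each of these genes overlapped in all comparisons of the 3 groups, with the exceptions of Edn2, Tnfaip6 and Lep.

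The other 7 lists stayed inside the central range in all 3 comparisons in the main setting. With the trend in length and GC content removed, endothelium in HFOB against control lay outside it, at percentile 2.34. In HFLN and HFOB against control their medians were 0.02 and -0.10 for endothelium, -0.03 and 0.01 for fatty-acid oxidation, 0.09 and 0.01 for inflammatory genes, -0.04 and -0.05 for insulin and glucose handling, 0.20 and 0.19 for lymphocytes (4 of 12 genes measured), -0.03 and 0.03 for macrophages, and -0.13 and -0.05 for oxidative stress.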

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

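Protein-coding rows only, removal of the length and GC trend and leaving out merged rows were chosen after the data were seen, and the other alternatives before. The counts of passing rows depended on the interval rule. Without it, a fold of at least 2 was met by 249 rows in HFLN against control, 216 in HFOB against control, 208 in HFOB against HFLN and 96 in both comparisons with control. Asking only that each value lie outside the other group's interval gave 88 rows in HFLN against control, 84 in HFOB against control (within 1.5 times), 64 in HFOB against HFLN and 42 shared. Both rules are looser by construction. Counting protein-coding rows only left 13, 24, 6 and 10 rows, since most passing rows are small RNA genes or have no symbol. With a pseudocount of 0.1 FPKM, no low-value filter, a minimum of 5 FPKM, a fold of 1.5, rescaling, every status or summed symbols, these 4 counts stayed within 1.5 times, at 34 to 48, 45 to 63, 23 to 35 and 19 to 23. Rescaling removed median shifts of -0.0024 and -0.0124. The correlation of both folds stayed between 0.536 and 0.588.

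The counts of lists that stood out also stayed within 1.5 times under each alternative run. With the mean in place of the median, 28 of 36 such lists stayed outside the central 95% with their direction and 7 came inside. The stromal matrix list in HFLN against control turned to -0.0887 under the mean, where Timp1 weighs more. With the length and GC trend removed 31 of 36 stayed outside. Removal also brought lists from inside to outside the central 95%. The endoplasmic reticulum stress list came to percentile 0.635 in HFLN against control. Endothelium came to 2.34 in HFOB against control, and ovulation genes to 99.71 in HFOB against HFLN. The immediate-early, interferon, oviduct and cilia, and cholesterol lists kept their side and direction in each comparison where they stood out, under every list alternative. No paired analysis was possible because the table gives 1 value per group and no replicate numbers. Leaving out replicates, a replicate block, fits of only the compared groups, array weights and correlation-aware set tests all need per-animal values and were not run. The deposited intervals, about 42.1% of the FPKM on either side in control, limit what can pass: in simulated data for HFLN against control, a factor of 2 was found in 8.0% of rows with the scaled and 30.0% with the deposited spread.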

Other observations

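Abundant protein-coding genes, picked after the data were seen as those with at least 10 FPKM in every group and the widest log2 folds, add further differences. Several were lower in both diet groups with overlapping intervals: Timp1, named above, was joined by Nupr1 at 1168 FPKM in control, 346 in HFLN and 371 in HFOB and by Tnfrsf12a, the receptor of the cytokine TWEAK, at 146.4, 53.2 and 44.7. Ramp1, a subunit of the calcitonin gene-related peptide receptor, stood at 64.8, 29.8 and 22.8. The cytokine feedback inhibitors Socs3 and Socs1 were lower mainly in HFOB, at 39.4, 31.4 and 13.6 FPKM and at 37.2, 23.9 and 14.4. Wfdc2, a secreted protease inhibitor of epithelia, was higher in both diet groups, at 31.3, 70.0 and 64.2 FPKM. Gpnmb, a glycoprotein of lipid-laden macrophages, stood at 12.3, 17.0 and 26.4, while the macrophage list as a whole did not stand out. Parvb, Cited1 and the interferon-induced Gbp3 were higher in HFLN than in both other groups, as was Irf7 at 14.3, 27.2 and 12.8 FPKM. None of these genes passed the rule.

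Of the tests below, that on histone genes and the count of small RNA were chosen after the results they measure had been seen. The other panels were written before their values were computed, but after the patterns had been noticed. All rest on group values, so whether a pattern comes from 1 animal or from all 3 is open.

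The immediate-early genes were lower in both diet groups. After the trend of log2 folds with transcript length and GC content had been removed, their median nearer to 0 was still -0.76, which argues against that trend as the cause. A general heat-shock reaction to handling would move the chaperone genes as well, but 12 heat-shock genes had medians of -0.0393 in HFLN and 0.0014 in HFOB. A reaction to handling that leaves chaperone genes unmoved was not tested by this panel. A difference in the stage of the ovulatory cycle stays open: a second panel of 15 measured genes induced around ovulation lay at percentile 2.565 in HFLN, just inside the bound set beforehand, and below all random lists in HFOB. Cycle stage is not given in the labels used here, 3 animals per group need not be balanced for it, and Edn2 and Tnfaip6 are themselves expressed in a brief window around ovulation. A control group with an animal near ovulation may therefore give the same picture as an effect of diet, which was not tested against it, and the time between death and freezing is untested too.

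Oviduct and cilia genes were higher in HFLN and lower in HFOB than in control. A second panel of 18 measured cilia genes, without overlap with the first, had a median of -0.77 between HFOB and HFLN with 18 of 18 lower. The pattern was thus not limited to the few markers first chosen. Both panels rest on the same group values and their genes may vary together, so the second does not bear on the source of the pattern. A candidate source is oviduct tissue left on the dissected ovary. A panel of 15 epithelial genes had a median of -0.27 between HFOB and HFLN, in the direction this needs but short of the -0.3 set beforehand. Against control 14 of the 15 were higher in HFLN with a median of 0.25. In HFOB 9 were higher and 6 lower with a median of 0.0171, so there the panel did not follow the cilia genes of the second panel, of which 17 of 18 were lower. Ovgp1, the abundant secreted protein of the oviduct, stood at 369, 432 and 307 FPKM in control, HFLN and HFOB, with an interval that reaches 0 in HFLN, and the surface of the ovary also expresses several of the epithelial genes. Carry-over and a difference in the ovary's own epithelium cannot be told apart with whole-tissue group values, and neither can the link to the interferon genes, which were high in the same group.

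Rmrp, Rpph1 and most histone genes were lower in HFLN than in both other groups. Other small RNA genes were mixed. Of 41 rows of small RNA other than microRNA, 25 were above 0 in every group, and the lowest value lay in HFLN for 17, in HFOB for 7 and in control for 1. Against that order, Rnu12 stood at 20.4, 3.53 and 0 FPKM in control, HFLN and HFOB, Snora61 was at 0 in both diet groups and Snord47 was seen in HFLN only, at 60.4 FPKM. Replication-dependent histone genes, whose RNA has no poly(A) tail, had a median log2 ratio of -1.64 in HFLN against control over 53 genes and 1.41 in HFOB against HFLN, in line with less untailed RNA carried through selection in HFLN. They were also lower in HFOB than in control for 39 of the 53 genes, with a median of -0.37. Across protein-coding genes the log2 fold of HFLN against control also rose with transcript length, at a Spearman rho of 0.252, which was 0.0977 in HFOB. With GC content the rho was -0.269 in HFLN and -0.0494 in HFOB, and the part of each was not separated. The shortest 10% of genes had a median of -0.14 in HFLN on the FPKM + 1 scale. That scale understates low genes, and the histone median is of plain ratios. Whether length alone reaches the histone difference is therefore not settled by these medians. Of 77 ribosomal protein genes, which are tailed and short, 71 were lower, with a median of -0.25. Selection, length and GC content may act together, through library preparation or RNA quality. Cmss1 at 25903, 3713 and 14044 FPKM, Filip1l at 6843, 1263 and 6612 and Lars2 at 2146, 512 and 1347 had the same order of groups, as did 191 of 260 rows without a symbol above 100 FPKM in being lowest in HFLN. A further structural RNA row had the status HIDATA in control, with a value of 0, so it was not compared with control. It stood at 1299 FPKM in HFLN and 4189 in HFOB. For Rmrp, Rpph1, histone and ribosomal protein genes, an effect of diet in HFLN is thus not separated from these technical explanations. The same holds for Cmss1, Filip1l and Lars2.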
